A study of Mus musculus with 5 samples.

How the data were processed

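Gene expression was measured on Affymetrix mouse arrays in microdissected ventromedial hypothalamus of C57Bl/6 mice, with 1 array for each of 5 groups: sham at 2 h, and 1 or 7 electroconvulsive shocks at 2 h or 6 h. The current was 25 mA with pulses of 0.5 msec at 100 pulses/sec for 1 sec, given through ear clip electrodes. The authors cut brain sections of 7 µm, took the nucleus by laser microdissection, pooled RNA of 2 or 3 animals per array and amplified 2 ng of it with the NuGEN Ovation Pico WTA kit. They hybridised 5 µg of labelled cDNA. The design describes a repeat of the array work on other animals, and those arrays were not used here.

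The deposited values are MAS5 signals, that is, 1 intensity per probe set on a linear scale with 1 decimal, per the submitters' processing notes and the values themselves. The software version, the target intensity and the detection calls are not given in the sources used here. The deposited intensity values were not at a common level: the trimmed mean per array was 82.5 for sham, 77.1 for 1 shock at 2 h, 115 for 1 shock at 6 h, 120.1 for 7 shocks at 2 h and 119.5 for 7 shocks at 6 h. Of all values, 87 were exactly 0. Correlations between arrays across genes were 0.898 to 0.919. The 3' to 5' ratio was 5.37 to 8.77 for the Gapdh controls and 0.593 to 1.10 for the beta-actin controls.

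The table held 22690 probe sets. The 64 controls, 691 probe sets with several gene symbols and 1555 with no symbol in the annotation used here were left out, leaving 20380, of which 20364 matched a RefSeq gene by gene ID with 0 symbols changed. A list name given by an older synonym was accepted only where no current gene bears that symbol. A pseudocount of 1.2, the 10th percentile of all values, was added before log2. Probe sets in the top 50% by mean over the 5 arrays were kept, which gave 10402 probe sets and 6650 genes, 2470 of them with more than 1 kept probe set. Each array was centred on the median of its kept probe sets, and a gene took the value of its kept probe set with the highest mean. With a list, members below this filter do not count as measured.

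There were 8 comparisons: each ECS array against sham, 7 shocks against 1 at each time, and 6 h against 2 h after each number of shocks. The sham was collected at 2 h, so the 6 h comparisons with it are not matched in time. No test of significance was possible with 1 array per group. Genes were called by a log2 difference of at least 1, which is 2-fold. The 4 comparisons with sham share 1 array. The pair of time comparisons share none, nor do the pair of shock number comparisons, and these pairs were described by the correlation and the overlap across genes. Counts for unchanged groups came from 100 simulations that drew scatter from genes of like brightness on these arrays. Each gene was drawn separately, so genes that vary together were not simulated. Array-specific genes were those at least 4-fold (log2 of 2) above or below all other arrays.

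The 28 gene lists were fixed in advance: immediate early transcription factors, activity-regulated effectors, MAPK and G-protein feedback, energy balance, neuropeptides and granins, growth factors, glucocorticoid response, inflammation, heat shock, circadian clock, sterol synthesis, glutamate and GABA receptors, potassium and calcium channels, oxidative phosphorylation, ribosomal proteins, Y-linked genes, and markers of the VMH, arcuate nucleus, PVN, other hypothalamic nuclei and the main brain cell types. A list's median is given as its percentile among 10000 random lists of equal size drawn from 20 bins of mean expression (seed 7), and lists with under 3 measured genes got no median. These percentiles describe the arrays and are not p-values. Lists share some genes. Marker lists of cortex and amygdala, thalamus and mammillary nuclei were added after the arrays were examined.

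Genes were named by rule: for each comparison with sham, the 8 genes furthest in each direction whose kept probe sets had 1 sign; for each pair of comparisons, the 10 genes per direction with the largest smaller difference; list members past 2-fold or among the 4 largest of their list; and the 8 per direction shared by all 4 comparisons with sham. Clones without a gene name were counted only. The count of dim deposited signals among the genes furthest from sham was added after the results were seen. The groups, comparisons, lists, naming rule and the alternatives were chosen before the data were examined, except where stated.

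The alternatives were no rescaling, quantile and cyclic loess normalization over all probe sets, a pseudocount of 0 or of 6.1 (the 25th percentile), no low value filter or the top 25% by mean, the mean of a gene's kept probe sets, leaving out cross-hybridising probe sets by suffix, and leaving out each ECS array from the shared counts. Leaving out the genes very low on the single-shock 6 h array was added later. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for the normalizations.

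The procedure was tested on simulated data with known changes put into the comparison of 1 shock at 2 h with sham. Of the 50 genes raised and 45 lowered by 1.5 on the log2 scale, 84.0% and 75.6% passed 2-fold in the right direction, as did 98.0% and all of the 50 raised and 38 lowered by 3. Of the unchanged genes 15.1% passed 2-fold as well, and 6.00% of 200 unchanged lists fell outside the central 95% of random lists. Those lists were 13 randomly drawn genes each, so they do not test lists whose genes vary together.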

Results

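The data were 5 Affymetrix arrays of mouse ventromedial hypothalamus (VMH), the hypothalamic nucleus best known for its part in satiety, energy balance and defensive and reproductive behaviour. C57Bl/6 mice under isoflurane received an electroconvulsive seizure (ECS), a brief current through ear clip electrodes, either 1 time or 7 times. Their brains were collected 2 h or 6 h after the last shock. Sham animals were handled in the same way without current and collected at 2 h. Each of the 5 groups (sham at 2 h, 1 shock at 2 h, 1 shock at 6 h, 7 shocks at 2 h, 7 shocks at 6 h) is represented by 1 array of RNA pooled from 2 or 3 animals. The titles and tissue fields name the VMH, whereas a descriptive field of the same samples says PVN. Of the PVN and supraoptic marker list, 2 genes were bright enough to be kept. The oxytocin gene Oxt read 16.4 on the sham array and 52.8 after 7 shocks at 2 h, and the thyrotropin-releasing hormone gene Trh read between 109 and 158 on all 5 arrays. The VMH transcription factor Nr5a1 read 94.8 on the sham array and between 67.3 and 158 on the others.

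The median signal per array was 23.4 for sham, 20.3 for 1 shock at 2 h, 26.9 for 1 shock at 6 h, 31.6 for 7 shocks at 2 h and 30.9 for 7 shocks at 6 h. Relative to sham, the kept probe sets of these 4 ECS arrays were shifted by -0.13, 0.40, 0.50 and 0.48 on the log2 scale, in the same order. Differences below are log2 differences after each array was centred on its own median, so they are relative to these shifts, and they cover 6650 genes. Readings quoted for single genes are the centred values on a linear scale with the pseudocount included, unless called deposited. No group has a replicate array, so no spread between replicates and no test of significance can be given. Genes were called higher or lower by size alone, at 2-fold, and the number of arrays limits the precision. In simulated arrays without any group difference, built from the scatter of these arrays, a mean of 969 genes passed 2-fold per comparison, over all 8 comparisons. That scatter also holds any real difference between the groups. Where genes had several kept probe sets, the log2 differences of the 2 brightest probe sets correlated at 0.128 to 0.274 across genes, and 55.6% to 67.7% of the genes past 2-fold had the same sign on the second probe set. Gene lists were set against 10000 random lists of equal size and brightness, and percentiles below refer to those. Of the 64 places among the genes furthest from sham, 58 rest on a signal below the median of its array and 19 on one below the 25th percentile of all values.

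At 2 h after 1 shock, the question was what a single seizure does to the VMH at the time matched to the sham. The activity-induced transcription factors stood highest of the lists. Fos read 185 against 12.6 in sham, a log2 difference of 3.87, and its partner Jun read 432 against 77.0 (2.49, with its other probe set at 2.37). The zinc finger factors Egr1 and Egr2 were higher by 2.53 and 2.46, and Klf10 by 2.45. The immediate early list had a median of 0.91 over 13 measured genes, above all of the random lists, with 12 members above 0 and 6 past 2-fold, and it was 1.65 in the brightest 25% of probe sets. Myc, a growth-associated factor, was its exception at -0.95.

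Activity-regulated effector genes were also higher in this comparison. Their median was 0.71 over 17 genes, above every random list, and 8 passed 2-fold in the higher direction against 0 in the lower. Arc, a synaptic scaffold that governs AMPA receptor trafficking, was higher by 3.13. Rgs4, which speeds the shut-off of G-protein signals, was higher by 1.88 and by at least 0.79 on its other probe sets. Nptx2, a secreted pentraxin that clusters AMPA receptors, differed by 1.68, and the neurotrophin Bdnf by 1.67. Nab2, a corepressor of Egr factors, differed by 1.67, and Gadd45b, a stress-inducible DNA demethylation factor, by 1.17. The postsynaptic scaffold Homer1 was higher by 1.30 on its brightest probe set, while its other probe sets ranged from 0.07 to 3.16.

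Energy balance genes had a median of 0.57 over 12 genes (percentile 99.6). Besides Bdnf, the leptin signal transducer Stat3 was higher by 1.31, while the cannabinoid receptor Cnr1 stood at -1.13. Sterol and lipid synthesis genes had a median of 0.37 (percentile 99.3) with no member past 2-fold. Among these enzymes, Msmo1 differed by 0.78, Lss by 0.71 and Idi1 by 0.58. Relative to the other arrays, however, the sham array itself was low for the sterol list, at -0.27 (percentile 1.87). The single-shock 2 h array lay at 0.08 on that measure (percentile 76.2). The sterol median against sham therefore cannot by itself be read as a rise after the shock. VMH markers had a median of 0.27 (percentile 90.1), which was -0.040 in the brightest 25% of probe sets. Of the glucocorticoid-responsive genes (median 0.26, percentile 94.3), Zbtb16 was higher by 2.10, Sgk1 by 1.74 and the clock gene Per1 by 1.11. The circadian list had a median of 0.37 (percentile 96.1), with Per3 at 1.49 and the clock output factor Dbp at -1.13, and Clock at 1.14 or -2.06 by its 2 probe sets. The cochaperone Dnajb1 read 3804 against 1915 (0.99). The phosphatase Dusp1, which switches off MAP kinases, was higher by 1.10, whereas the MAPK and G-protein feedback list as a whole lay at 0.12.

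Among the genes furthest above sham were Fos, the small GTPase Rrad (3.52), Arc, the Ras relative Eras (2.83), Pcnx (2.67), the deadenylase subunit Cnot3 (2.66) and Adap2 (2.60). Furthest below sham were Tmem97 (-3.72), Nepro (-3.38), the purine synthesis enzyme Gart (-3.16), Grtp1 (-3.12), Dnlz (-2.85), Gtf2ird1 (-2.80), Spg21 (-2.73) and the peroxisomal thiolase Acaa1b (-2.68). The Gart value rests on a deposited signal of 5.4, below the 25th percentile of all values. In total 398 genes were at least 2-fold higher and 418 lower, a share of 48.8% higher. Without rescaling of the arrays the split was 291 to 572, or 33.7% higher. The sham and single-shock 2 h arrays were the dimmest, and the 3' to 5' signal ratio of Gapdh, a sign of RNA or amplification quality, was 6.67 and 8.77 on them against 5.37 to 5.88 on the others. The same ratio of beta-actin did not set them apart, at 0.799 and 0.889 against 0.593 to 1.10.

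**Figure D1:**
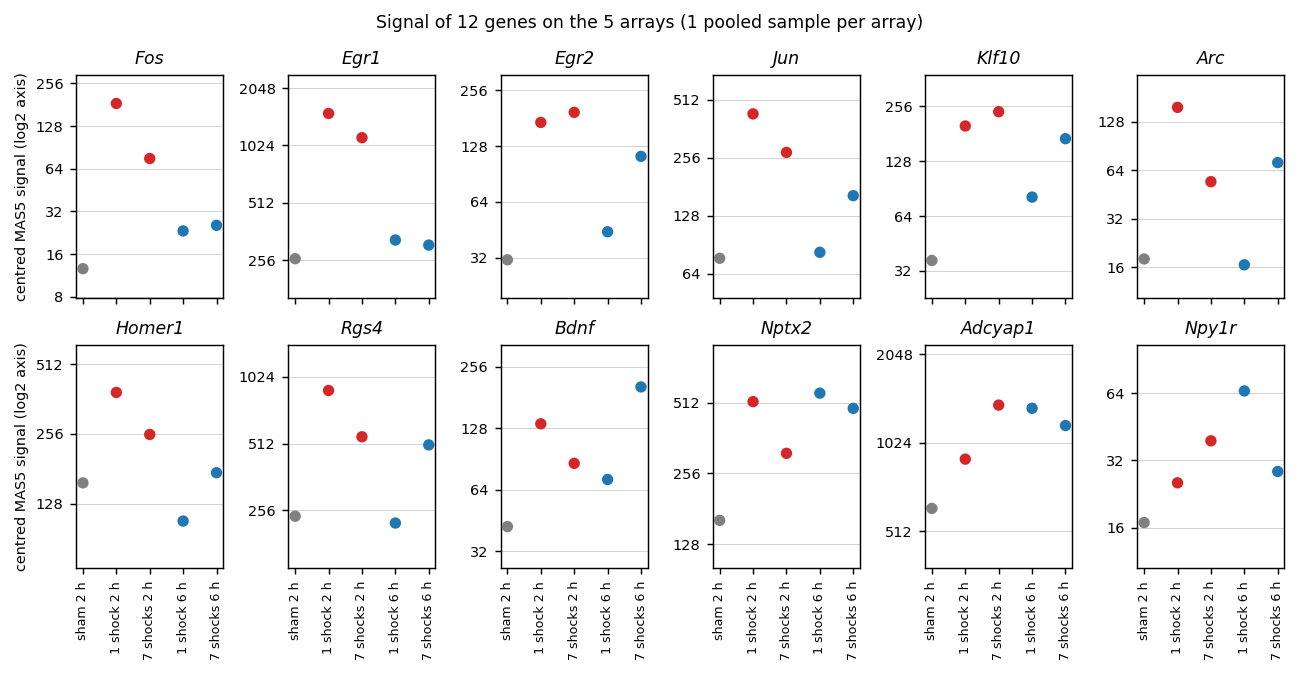
Centred signal (log2 scale) of 12 genes on the 5 arrays, 1 point per array and no error bars because each group has 1 array. They are immediate early and effector genes, with the peptide gene Adcyap1 and the receptor gene Npy1r. Fos lay 3.87 above sham 2 h after 1 shock and 0.89 above it at 6 h.

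At 2 h after 7 shocks, the comparison asked how the VMH of repeatedly treated animals differed from sham at the matched time. The immediate early list was again high, with a median of 0.87 over 13 genes (percentile 99.99), 11 members above 0 and 6 past 2-fold, and it was 1.38 without rescaling. Klf10 differed by 2.71, Egr2 by 2.64, Fos by 2.58, Egr1 by 2.11, Jun by 1.82 (1.71 on its other probe set) and the small Maf factor Maff by 1.65. Effector genes had a median of 0.33 (0.84 without rescaling), at percentile 96.5 and so inside the central 95% of random lists. Arc read 54.3 against 18 in sham, Nab2 differed by 1.51 and Bdnf by 1.03, while the probe sets of Rgs4 ranged from -0.14 to 1.19.

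In the same comparison, neuropeptides and granins had a median of 0.44 over 21 genes (percentile 99.9), with the enkephalin precursor Penk at 1.14, the prohormone convertase Pcsk1 at 1.02 and Adcyap1, which encodes the VMH peptide PACAP, at 1.17. VMH markers had a median of 0.66 over 6 genes (percentile 99.85, with 0.32 in the brightest 25% of probe sets and 1.17 without rescaling), although 3 of the 6 (Adcyap1, Bdnf and Nptx2) also belong to the activity, peptide or energy lists. The remaining 3 differed by less, with Nr5a1 at 0.38, the vesicular glutamate transporter Slc17a6 at 0.20 and Cbln1 at 0.05. Relative to the other 4 arrays, the sham array itself was low for both lists, at -0.61 for VMH markers (percentile 0.06) and -0.30 for neuropeptides (percentile 0.36). On the same measure this 7-shock array lay inside the central 95% of random lists, at 0.03 and 0.12 (percentiles 63.0 and 93.4). In the energy balance list, the insulin and leptin signal phosphatase Ptpn1 differed by 1.63 and the neuropeptide Y receptor Npy1r by 1.21 (list median 0.41, percentile 96.95). General neuron markers had a median of 0.35 (percentile 99.9) and 12 of 13 members above 0. The circadian list had a median of 0.44 (percentile 98.2), which was -0.10 in the brightest 25% of probe sets, with Per1 at 1.36 and Dbp at -1.17 (0.22 on its other probe set).

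Microglial markers were lower than sham, with a median of -0.53 over 8 genes (percentile 0.59). The purinergic receptor P2ry12 stood at -2.24, Aif1 at -1.58 and the lysosomal gene Laptm5 at 0.82. The growth factor receptor Csf1r was at -1.52 on its brightest probe set and 0.10 on its other, and the probe sets of the complement gene C1qb spanned -0.56 to 0.90. That median was 0.12 when the brightest 25% of probe sets alone were used. Arcuate markers had a median of -0.70 over 4 genes (percentile 1.86), with Tac2 at -1.68 and Npy at -1.06. Cytosolic ribosomal proteins had a median of -0.20 over 13 genes (percentile 0.62), which was 0.30 without rescaling, where all genes had a median of 0.51.

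The genes furthest above sham were Kansl1 (3.36, but 0.01 on its other probe set), the splicing factor Sf3a2 (3.12), the recombination repair gene Rad54l (2.90), the lysosomal sialidase Neu1 (2.84), St3gal1 (2.79), Sfxn4 (2.72), Klf10 and the phosphodiesterase Pde10a (2.66). Furthest below were Zfp574 (-3.79), the laminin chain Lamc1 (-3.35), the pentose phosphate enzyme Rpia (-3.30), Polr3gl (-3.16), Rpp25 (-3.08), Toe1, Grtp1 and the ferroxidase Heph (-2.93). Sf3a2, Rad54l, Sfxn4, Rpia and Toe1 rest on deposited signals of 5.5 or less, below the 25th percentile of all values, so their exact sizes and order are not reliable. The counts were 437 higher and 447 lower (49.4% higher). Without rescaling they were 1324 and 143 (90.3% higher).

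At 6 h after 1 shock, a later stage of the response was compared with the sham, which was collected at 2 h, so the time was not matched. Immediate early genes were nearer to sham, with a median of 0.50 (percentile 98.7). Klf10 was at 1.16, Klf6 at 1.48 (-0.11 on its other probe set) and Ier5 at -1.21, while Egr1 read 326.8 against 260.9 (0.33) and Fos 23.3 against 12.6 (0.89). Relative to the other arrays, the immediate early list was low on the sham array (-0.70, percentile 0.01) and on this array (-0.69, percentile 0.015). The median of 0.50 therefore cannot by itself be read as a lasting rise. Against sham, effectors had a median of -0.10 (percentile 27.2), although Nptx2 was at 1.80. The MAPK and G-protein feedback list was lower than sham, with a median of -0.84 over 9 genes (percentile 0.05). Its members Dusp14, Errfi1 and Spry2, all brakes on growth factor or kinase signals, stood at -1.86, -1.27 and -1.21.

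VMH markers were high here too, at a median of 0.75 (percentile 99.7, and 1.15 without rescaling) with all 6 members above 0, among them Adcyap1 at 1.13 and Nr5a1 at 0.73. Potassium and calcium channel genes had a median of -0.62 over 17 genes (percentile 0.16), with Kcnc1 at -1.46, Cacna1d at -1.31 and Kcnd3 at -1.30. The circadian list had a median of -0.51 (percentile 0.67), led by Hlf at -3.15. Gad1, which makes GABA, was at -1.81 (-2.24 on its other probe set), with a GABAergic list median of -0.43 over 3 genes (percentile 8.87). Npy1r, at 1.95, and the inducible chaperone Hspa1a, at 2.16, were among the list members furthest above sham.

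This array stood apart from the other 4 by a set of very low genes. On it 16 genes were at least 4-fold below every other array, against 4 to 6 genes on any other array, and 5 were 4-fold above. These genes were picked out after their values were seen. The dap poly-A control signal, over the median of its array, was 6.86 on this array and 2.39 to 3.42 on the others. The low set included Igfbp4, a carrier of insulin-like growth factors (4.34 against 164 or more), the cortical neuron transcription factor Tbr1 (1.90 against 63.9 or more), the peptides Vip and Cck, the clock output factor Hlf, and Mef2c (59.4 against 343.4 or more). Igfbp4 was at -5.24 against sham, with its 4 probe sets between -5.24 and -1.64. The related carrier Igfbp5 was at -3.56, and at -2.10 on its other probe set. In the same array, markers of cortical and amygdalar excitatory neurons had a median of -0.30 relative to the other arrays (percentile 1.85), a list written after the arrays were examined. That list leaves out genes of the low set.

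The other genes furthest below sham were Tbr1 (-5.13), Znrf2 (-3.91), Pdzrn3 (-3.89), Lamc1 (-3.87), Vip (-3.66) and Erdr1 (-3.43). The deposited signals of Igfbp4, Tbr1, Znrf2, Pdzrn3 and Vip on this array were 3.6 or less, below the 25th percentile of all values, so their exact sizes and order are not reliable. With a pseudocount at that percentile Igfbp4 was at -4.26 and Tbr1 at -3.49. Furthest above were the ubiquitin-like modifier Urm1 (4.04), Hspa1l (3.83), Sf3a2 (3.61), Nfic (3.38), Sfxn4 (3.29), the Wnt antagonist Sfrp2 (2.95), Il13ra1 (2.91, and 2.26 on its other probe set) and the sorting nexin Snx6 (2.85). Sf3a2 and Sfxn4 rest on deposited sham signals of 4.8 and 4.4, also below the 25th percentile of all values. The counts were 448 higher and 489 lower (47.8% higher). Without rescaling they were 1132 and 231 (83.1% higher).

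**Figure D2:**
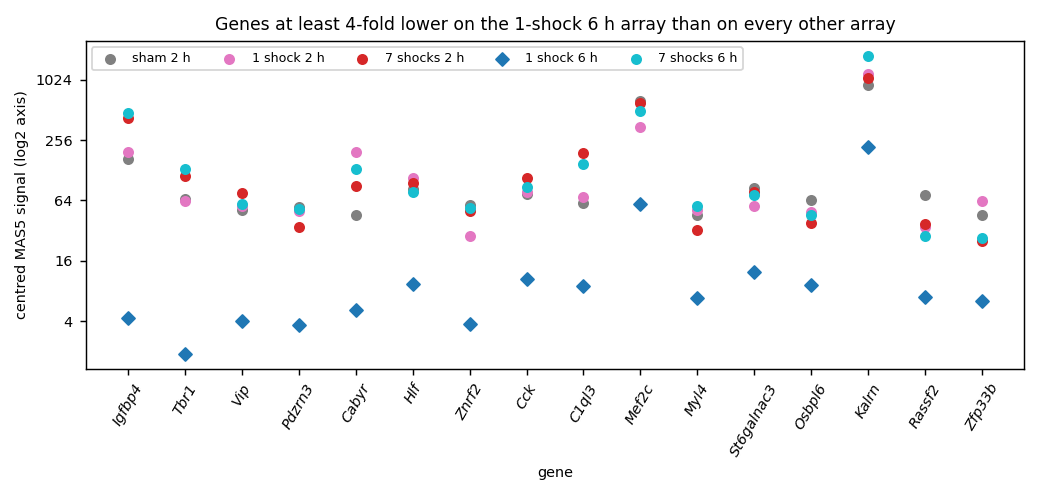
Centred signal (log2 scale) of the 16 genes that were at least 4-fold lower on the single-shock 6 h array than on each other array, 1 point per array and gene. Igfbp4 read 4.34 there and 164 or more on the other arrays.

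At 6 h after the last of 7 shocks, again against the 2 h sham, effector genes were high. Their median was 0.53 over 17 genes (percentile 99.7), with 6 members at least 2-fold higher and 3 lower. Bdnf was at 2.27, Arc at 1.99, Nptx2 at 1.58, Nab2 at 1.25, Gadd45b at 1.13 and Rgs4 at 1.07, against Tiparp at -1.24 (0.02 on another probe set), Nfil3 at -1.16 and Pcdh8 at -1.04. Of the immediate early genes (median 0.45, percentile 98.25), Klf10 was at 2.22, Egr2 at 1.85 and Fos at 1.02, Jun at 1.08 or -0.49 by its 2 probe sets, whereas Egr1 was at 0.24 and Myc at -1.74. Relative to the other arrays, the sham array was low for the immediate early list (-0.70, percentile 0.01). On the same measure this array lay at -0.18 (percentile 11.6), inside the central 95%. Neuropeptides and granins had a median of 0.46, above all random lists, with 19 of 21 members above 0, against the sham array that was low for this list. In the 4 comparisons without sham the list lay inside the central 95% of random lists, with medians of 0.09 to 0.21, while this array lay 0.25 above the other 4 (percentile 99.2). Penk was at 1.68, the granin Scg2 at 0.95 and the substance P precursor Tac1 at 0.77.

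VMH markers had a median of 0.70 against the low sham array (percentile 99.8), which was 1.18 without rescaling and 0.40 in the brightest 25% of probe sets. Relative to the other 4 arrays this array lay at 0.26 for them (percentile 94.6), inside the central 95%. Neuron markers had a median of 0.29 (percentile 99.2). Microglial markers were lower than sham, with a median of -0.55 (percentile 0.51), P2ry12 at -1.94 and Csf1r at -1.17 (0.24 on its other probe set). Relative to the other 4 arrays, however, they lay inside the central 95% on this array (-0.18, percentile 13.8) and on the sham array (0.21, percentile 93.0). Growth and angiogenic factors had a median of -0.74 over 6 genes (percentile 2.73), with Igfbp5 at -1.92, Igfbp3 at -1.27 and the platelet-derived factor Pdgfa at 1.02. The serotonin receptors parted, Htr1b at -1.48 and Htr2c at 1.10. Glucocorticoid-responsive genes had a median of -0.037 over 16 genes (percentile 30.8), with the cochaperone Fkbp5 at 1.31, Sgk1 at 1.54 and Cables1 at -1.08. Markers of cortical and amygdalar neurons lay 0.42 above the other arrays on this array (percentile 99.7).

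Furthest above sham were Sf3a2 (5.10), Trim26 (3.72), the centriole kinase Plk4 (3.64), Rad54l (3.36), Adap2 (3.32), the actin crosslinker Actn1 (3.09), the cholesterol carrier Stard4 (3.05) and the arginine methyltransferase Prmt6 (2.92). Furthest below were Tmem97 (-5.46), Frmd4b (-4.48), Rpp25 (-3.80), Zfp810 (-3.71), Asb4 (-3.50), Erdr1 (-3.41), Ninj1 (-3.38) and Palm (-3.19). The deposited signals of Tmem97, Frmd4b, Zfp810 and Asb4 on this array were 6 or less, below the 25th percentile of all values. So were the sham signals of Sf3a2 (4.8) and Rad54l (5.2), and the exact sizes and order of these genes are not reliable. With a pseudocount at that percentile Tmem97 was at -4.50 and Sf3a2 at 4.29. The counts were 451 higher and 470 lower (49.0% higher). Without rescaling they were 1314 and 169 (88.6% higher).

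Genes at least 2-fold from sham in the same direction in all 4 ECS groups numbered 46 higher and 39 lower. Sf3a2, Sfxn4, Cnot3, the giant scaffold Ahnak, Hmbox1, the laminin chain Lama1 and Tnfrsf18 led the higher side, Ahnak with differences between 1.84 and 2.18. Apart from Ahnak, all of these leading genes had deposited sham signals of 7.2 or less, below the sham median, so their sizes depend on dim readings. Dcx, a microtubule protein of young neurons, belonged there by its brightest probe set alone, since its other probe set disagreed. Grtp1, Rpp25, Tmem97, Dnlz, Arhgap35, Dtnbp1 and Tubb6 led the lower side, together with Hdlbp, whose 5 probe sets disagreed. All 4 comparisons share the sham array, and simulated unchanged groups against 1 shared control gave means of 68.2 higher (50 to 85) and 53.8 lower (36 to 74). The 46 higher genes were fewer than in any simulation, but numbered 92 without rescaling and 22 with a pseudocount at the 25th percentile. The 39 lower genes were fewer than the mean, and numbered 13 without rescaling. The simulations pooled the scatter of all 5 arrays. Their covariance across genes between comparisons with sham was 0.257 to 0.258, above the observed 0.215 to 0.252. The lower counts therefore cannot be read as less sharing than unchanged groups would give. Outside this ranking, Sgk1, a kinase induced by glucocorticoids, was 1.16 to 1.74 above sham in the 4 groups, and Dbp was between -1.57 and -0.96, although its other probe set was at 0.22 after 7 shocks at 2 h.

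The difference between 6 h and 2 h was taken after 1 shock and after 7 shocks, in comparisons that share no array and use no sham. Immediate early genes were lower at 6 h in both. After 1 shock their median was -1.30 over 13 genes, below all random lists, with 8 members at least 2-fold lower, and -0.77 without rescaling. After 7 shocks it was -0.74 (percentile 0.01), with 3 members 2-fold lower, and -0.45 in the brightest 25% of probe sets. Egr1 was the most even of them, at -2.21 and -1.87. Fos was at -2.99 and -1.57, Ier3 at -1.59 and -1.15, and Jun at -2.38 and -0.74. Per1 was at -1.04 and -1.07, and Sertad1, a cell cycle and transcription regulator, at -2.07 and -2.28.

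Effector genes did not follow the same course after 1 and 7 shocks. After 1 shock their median was -0.90, below all random lists and -0.38 without rescaling. Arc was at -3.25, Tiparp at -2.36, Rgs4 at -1.99 and Homer1 at -1.85. After 7 shocks it was 0.25 (percentile 91.3), with 2 members at least 2-fold higher and 2 lower, Bdnf at 1.24 and Arc at 0.39. The difference between these differences had a median of 1.08 (percentile 99.97). Relative to the other arrays, effectors were at -0.58 on the single-shock 6 h array (percentile 0.02) and 0.65 on the single-shock 2 h array (percentile 100). The single-shock 6 h array also held the 16 very low genes. Cortical and amygdalar markers were at -0.30 on it and 0.42 on the 7-shock 6 h array. MAPK feedback genes had medians of -0.81 (percentile 0.26) after 1 shock and 0.06 after 7, and a difference of 1.04 (percentile 99.6). Dusp1 was at -1.28 and 0.06, and Errfi1 at -1.88 and 0.22.

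Circadian, glucocorticoid-responsive and neuron genes also had negative medians for 6 h minus 2 h after 1 shock. Circadian genes had a median of -0.67 (percentile 0.09), and -0.38 (percentile 3.23) after 7 shocks. Glucocorticoid-responsive genes had one of -0.29 (percentile 1.75), with Zbtb16 at -3.11 and Ddit4 at -1.15, and neuron markers one of -0.16 (percentile 0.975). Without rescaling both were above 0, at 0.24 and 0.37, but below the median of all genes, which was 0.59. Arcuate markers differed by 0.14 after 1 shock and by 1.28 after 7 shocks (percentile 99.99), where the neurokinin B gene Tac2 was at 2.43, Npy at 1.51 and Pomc at 1.05. After 7 shocks, growth and angiogenic factors had a median of -0.82 (percentile 1.44) and energy balance genes one of -0.51 (percentile 1.29), with Htr1b at -1.70 against Htr2c at 1.84.

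Among all genes, those lowest at 6 h in both time comparisons were Otub2, Sertad1, the collagen chain Col1a2, Eras, the gamma-secretase subunit Aph1a, Egr1, Ganab, the carbonic anhydrase Car4, the ciliary neurotrophic factor receptor Cntfr and Abhd17c. Highest in both were the ankyrin Ank1 (2.10 and 2.12), Heph, Zfand2a, Cks1b, the corepressor Tle4 (1.83 and 1.71), Gart, Prps2, Nkd2, Tfb1m and Znrd1as. The probe sets of Ganab, Gart, Ank1, Cntfr and Zfand2a disagreed in sign in 1 or both comparisons. After 1 shock 493 genes were higher at 6 h and 505 lower (49.4% higher), and without rescaling 1575 and 175. After 7 shocks the counts were 419 and 442 (48.7% higher), and 46.6% were higher without rescaling. In all, 52 genes were higher in both and 60 lower in both, where independence gives 31.1 and 33.6, and simulated unchanged arrays gave 37 to 66 and 33 to 73. Without rescaling 116 were higher in both and 31 lower. The correlation across genes was 0.0021 (Spearman -0.016), with the caveat that genes are not independent replicates.

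**Figure D3:**
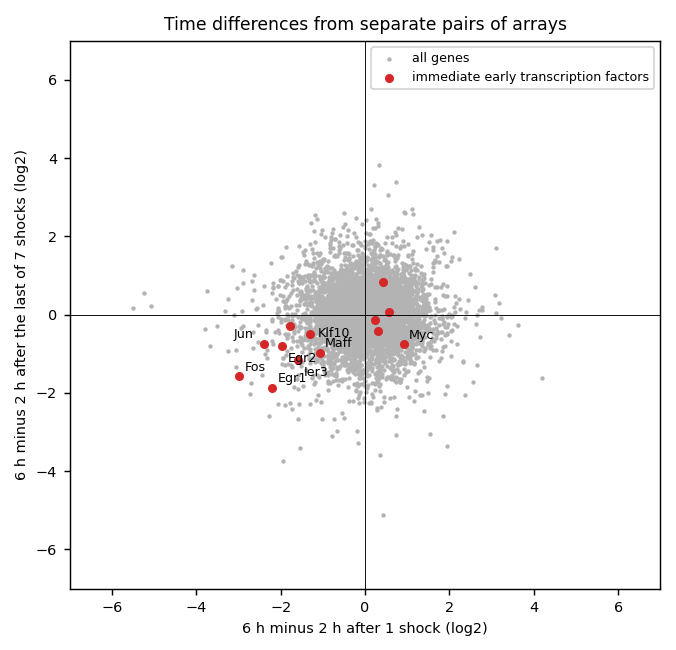
Log2 difference of 6 h minus 2 h after 1 shock (horizontal) and after 7 shocks (vertical), 1 point per gene, with immediate early genes in red. Egr1 lies at -2.21 and -1.87, and the correlation over all 6650 genes is 0.0021.

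Repeated and single shocks were compared at 2 h and at 6 h, again without a shared array. At 2 h effector genes were lower after 7 shocks than after 1, with a median of -0.65 over 17 genes (percentile 0.06) that was -0.01 without rescaling, where all genes had a median of 0.63. The single-shock 2 h array had the lowest median signal and the highest Gapdh 3' to 5' ratio, though not the highest beta-actin ratio. Only 2 of the 17 genes were above 0. Arc was at -1.54, Gadd45b at -0.94, Rgs4 at -0.69 and Bdnf at -0.64. Immediate early genes had a median of -0.14 (percentile 24.5) with Fos at -1.29 and Egr2 at 0.18. At 6 h effectors had a median of 0.31 (percentile 93.9), with Arc at 2.11, Sik1 at 1.51, Gadd45b at 1.45 and Rgs4 at 1.17.

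Arcuate markers separated the 6 h arrays. Their median was 1.25 over 4 genes (percentile 99.86), with Npy at 1.99, Tac2 at 1.47, Pomc at 1.04 (0.74 on its other probe set) and Cartpt at -0.61, against a median of -0.34 at 2 h. The difference between these 2 comparisons was 1.59 (percentile 99.9). On the 7-shock 6 h array itself these markers lay 1.08 above the other 4 arrays (percentile 99.96), with 3 of the 4 past 2-fold. Against sham that array was at 0.58 (percentile 95.0, inside the central 95%), with 0 genes 2-fold higher. The arrays of 1 shock at 2 h, 7 shocks at 2 h and 1 shock at 6 h were below sham, at -0.52, -0.70 and -0.52. Channel genes were higher after 7 shocks than after 1 at 6 h, with a median of 0.69 (percentile 99.8), Cacna1d at 2.39 and Cacng3 at 1.87, next to a median of 0.42 at 2 h (percentile 97.4). Relative to the other arrays, the single-shock 6 h array was low for them (-0.51, percentile 0.18). The 7-shock 6 h array lay at 0.12 on that measure (percentile 73.9) and at 0.07 against sham (percentile 66.3). Neuron markers were higher after 7 shocks at 2 h (0.27, percentile 99.8) and at 6 h (0.17, percentile 99.4), where Nefm was at 1.27, Syt1 at 1.09 and Rbfox3 at 1.07. Oligodendrocyte markers had a 6 h median of 0.34 (percentile 98.2), with Cldn11 at 0.88, which was -0.09 in the brightest 25% of probe sets. Ribosomal protein genes had a 6 h median of -0.33 (percentile 2.40). The 6 h comparison uses the single-shock array with the 16 very low genes, and the cortical and amygdalar markers stood at -0.30 on that array and 0.42 on the 7-shock array.

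Genes highest after 7 shocks at both times were Myh3 (2.97 and 3.69), the catenin Ctnnd1 (2.11 and 2.62), the actin-responsive coactivator Mrtfa, the DNA ligase Lig1, Ogfod3, Tgfb2, Crym, Smc4, Chst11 and Trim26. Lowest at both were Smo, the Hedgehog signal transducer (-3.56 and -1.61), Mob1a, the transglutaminase Tgm2, Rpia, Nipsnap3b, Crlf3, the acetyltransferase Kat2a, Arid2, Man2c1os and 1 unnamed clone. The probe sets of Tgm2, Mob1a, Smc4 and Kat2a disagreed in sign in 1 or both comparisons. At 2 h 460 genes were higher after 7 shocks and 454 lower (50.3% higher), and 1769 and 104 (94.4%) without rescaling. At 6 h the counts were 526 and 571 (47.9% higher), and 655 and 469 (58.3%) without rescaling. Both times together, 67 genes were higher and 68 lower, against 34 to 69 and 37 to 67 in simulated unchanged arrays, and 228 and 15 without rescaling. The correlation across genes was 0.063 (Spearman 0.055), and the largest simulated one was 0.037, but with no low value filter the correlation was 0.024. The simulations drew each gene separately, so genes that vary together could give larger values in unchanged arrays. The excess over 0.037 therefore does not show a shared effect of shock number.

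Across the 26 lists with at least 3 measured genes and the 8 comparisons, 40 of 208 medians lay outside the central 95% of random lists. If the genes of a list varied independently, 10.4 would be expected. Genes of a list can vary together between samples for any reason, so the excess by itself does not show an effect of the shocks. Several groups lay inside it in all 8 comparisons. Astrocyte markers had medians between -0.19 and 0.08 over 13 genes, with the glycolytic enzyme Aldoc between -0.44 and 0.27. Oxidative phosphorylation genes had medians between -0.16 and 0.17 over 21 genes, none past 2-fold. Heat shock and ER stress genes had medians between -0.08 and 0.23, and glutamate and GABA receptor subunits between -0.32 and -0.01. For the latter list, however, the difference between the 6 h and 2 h contrasts of 7 shocks with 1 had a median of -0.94 over 9 genes (percentile 0.41). The 4 inflammation and reactive glia genes had medians between -0.40 and 0.45, although the intermediate filament Vim was 0.24 above sham after 1 shock at 2 h and 1.02 to 1.28 above it in the other groups. Its probe sets disagreed in sign in both single-shock groups. The 3 Y-linked genes (Eif2s3y, Kdm5d and Uty) had medians between -0.71 and 0.38.

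Endothelial and pericyte markers had medians between -0.50 and 0.52 over 8 genes, inside that range throughout, with the barrier transporters Slco1c1 at -1.15 and Slco1a4 at -1.27 at 2 h after 1 shock. Markers of other hypothalamic nuclei had medians between -0.37 and 0.57 over 5 genes, and ependymal and tanycyte markers between -0.42 and 0.62 over 4 genes, with the tanycyte deiodinase Dio2 at -1.36 at 6 h after 1 shock. None of the choroid plexus and blood markers was bright enough to be kept.

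**Figure D4:**
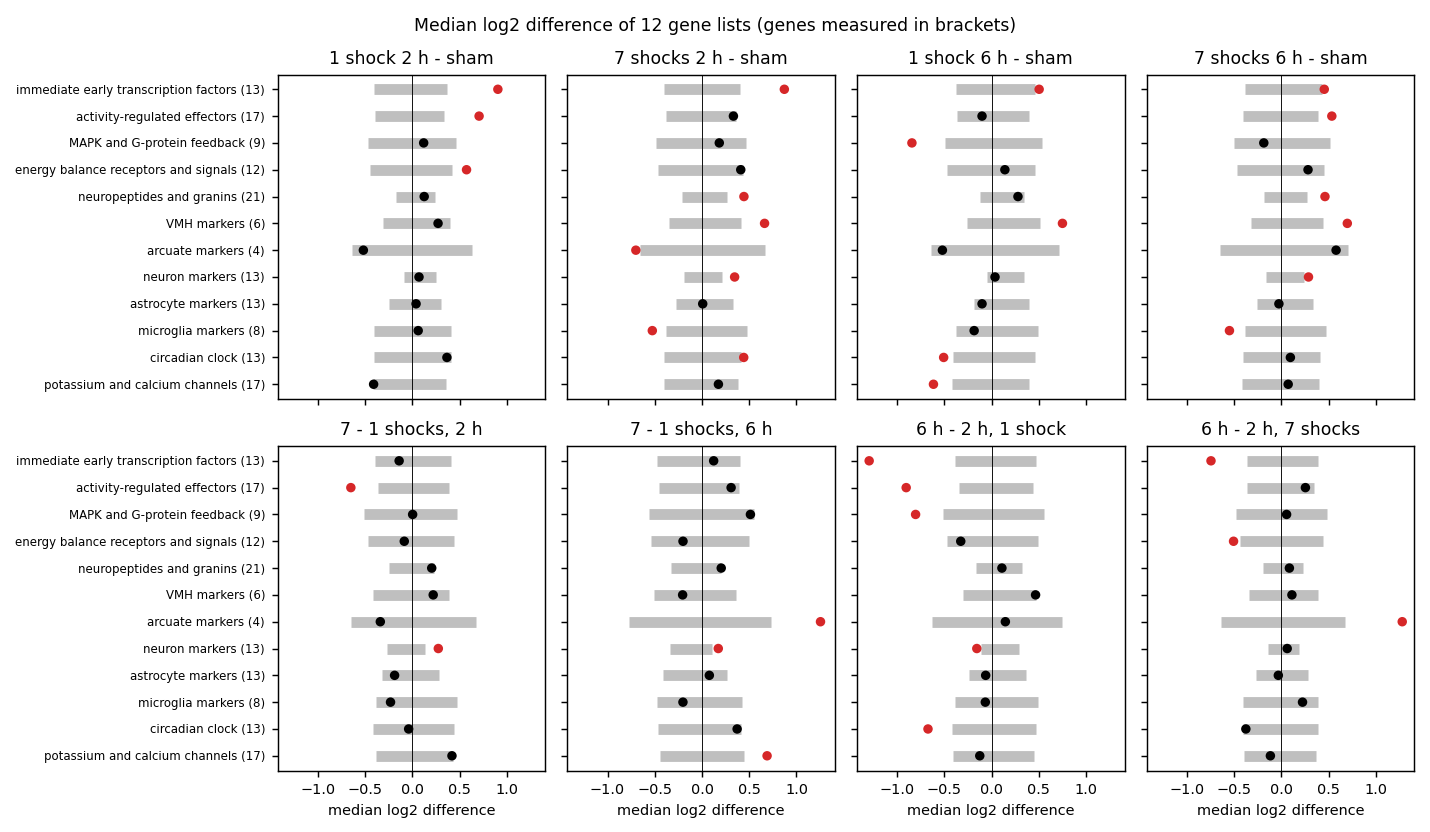
Median log2 difference of 12 gene lists in the 8 comparisons, with grey bars for the central 95% of 10000 matched random lists and red points where the median lies outside it. The immediate early list is at 0.91 and 0.87 at 2 h after 1 and 7 shocks, and at -1.30 and -0.74 for 6 h minus 2 h.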

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

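The tests on other probe sets of the same genes, on the time comparisons without sham, and on effectors against immediate early genes, with the limits for its gap, were chosen after the result was seen. Every pattern here rests on 1 array per group, and differences between groups had no replicate test.

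Activity-regulated effectors differed between comparisons of the same kind, by a median of 1.08 (percentile 99.97). For 6 h minus 2 h their median was -0.90 after 1 shock and 0.25 after 7 shocks, and for 7 shocks minus 1 it was -0.65 at 2 h and 0.31 at 6 h. The positive medians lay inside the central 95% of random lists (percentiles 91.3 and 93.9). On the single-shock 6 h array, which held the 16 very low genes, effectors were at -0.58 relative to the other arrays (percentile 0.02). The MAPK and G-protein feedback list had medians of -0.81 and 0.056 for 6 h minus 2 h after 1 and 7 shocks. It lay outside the central 95% on the single-shock 6 h array alone, at -0.79 relative to the other arrays (percentile 0.08). Arcuate markers had medians of -0.34 and 1.25 for 7 shocks minus 1 at 2 h and 6 h. Outside the gene measurements, the dap poly-A control probe sets, over the median of their array, read 6.86 after 1 shock at 6 h, against 2.75 on the sham array, 2.39 after 1 shock at 2 h, 2.97 after 7 shocks at 2 h and 3.42 after 7 shocks at 6 h.

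The 16 genes at least 4-fold lower on the single-shock 6 h array, among them Igfbp4, Tbr1, Vip, Hlf and Mef2c, are the pattern most in need of a second array. Defects of single probe sets are argued against, for 4 of these genes alone, by their 9 other kept probe sets (median -2.45, all lower). A brightness effect that depends on signal level is argued against by 13 of the 16 keeping the 4-fold gap under cyclic loess. Less cortex or amygdala tissue in that dissection may have contributed, and stays open: markers of excitatory neurons there had a median of -0.304 over 10 genes, with Lamp5, Camk2a, Crym and Itpka at least 2-fold lower. That median met neither the limit for it (-1 or lower) nor the limit against it (above -0.3). Genes of the pattern itself, such as Tbr1, were left out, so the test rests on the remaining markers alone. An effect of a single shock at 6 h stays open as well, because 1 array carries that group.

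Immediate early genes were higher at 2 h in both ECS groups. A brightness effect that depends on signal level is argued against by cyclic loess, under which the smaller of the 2 list medians was 0.84. Loess removes the overall shift between the arrays as centring does, so it cannot test that shift. Without rescaling the list kept its direction. A chance low reading of the sham array cannot be the whole cause, since the 6 h minus 2 h medians, which do not use it, were -0.74 or lower. A response to the seizures is the hypothesis that remains of those weighed, but dissection, pooling and time of day were not tested.

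Effector genes were lower at 2 h after 7 shocks than after 1. Cyclic loess left the list median at -0.67, which argues against a brightness effect that depends on signal level. It removes the overall shift between the arrays as centring does, so it cannot test that shift. Without rescaling the list median was -0.014, where all genes had a median of 0.63. A general shift of activity-dependent genes down on the 7-shock array stays open: the immediate early median was -0.14 with 9 of 13 below 0, a gap of 0.51 to the effectors (member SD 0.49) that 2.81% of random relabellings of both lists reached. Relative to the other 4 arrays, effectors were at -0.03 (percentile 43.4) and immediate early genes at 0.63 on the 7-shock array, and effectors at 0.65 on the single-shock array. A weaker effector response after repeated seizures may account for the difference, as a hypothesis from 1 array on each side, with a higher reading on the single-shock array equally open.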

How the results depend on the processing

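The setting that leaves out the genes very low on the single-shock 6 h array was chosen after the data were seen, and no count or list median moved past the limits set under it. No paired analysis was possible because each group has 1 array of pooled animals. A count was within the limits if it stayed within a factor of 1.5, and a correlation if it moved by less than its bootstrap margin (95%). A list median had to move by less than 1 SD of random-list medians, and a gene by less than the SD of genes of like brightness. A named gene reversed if its sign turned, and a list median only if it had also been outside the central 95%. Against the values reported, 195 of the counts and correlations under the alternatives were within the limits set and 73 moved; of list medians, 1776 stayed within, 250 moved and 6 reversed; of named genes, 4067 stayed within, 59 moved and 13 reversed. The immediate early list kept its direction under all settings, with medians of 0.63 to 1.65 and 0.83 to 1.38 for 2 h minus sham after 1 and 7 shocks, and of -1.60 to -0.77 and -0.76 to -0.45 for 6 h minus 2 h. Low signal limits the rest: the SD of log2 differences was 0.89 to 1.04 in the dimmest 25% of genes and 0.39 to 0.46 in the brightest.

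Without rescaling, where the arrays' shifts enter every difference, higher and lower genes numbered 1324 and 143 (7 shocks 2 h against sham), 1132 and 231 (1 shock 6 h), 1314 and 169 (7 shocks 6 h), 1769 and 104 (7 shocks against 1 at 2 h), and 1575 and 175 (6 h against 2 h, 1 shock). In both time comparisons 116 were higher and 31 lower, in both shock number comparisons 228 and 15, and against sham in all 4 groups 92 and 13. Immediate early medians were 1.38 (7 shocks 2 h against sham) and -0.77 (6 h against 2 h, 1 shock). Effector medians were 0.84 (7 shocks 2 h against sham), -0.014 (7 shocks against 1 at 2 h) and -0.38 (6 h against 2 h, 1 shock). VMH medians against sham were 1.17 (7 shocks 2 h), 1.15 (1 shock 6 h) and 1.18 (7 shocks 6 h). Neuron (0.37) and glucocorticoid medians (0.24) for 6 h against 2 h after 1 shock reversed in sign, as did the ribosomal one for 7 shocks at 2 h against sham (0.30). All genes had medians of 0.59 and 0.51 in these comparisons, so the lists still lay below the median of all genes.

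Without a low value filter more genes were counted. Higher and lower genes against sham were 1685 and 1357 (1 shock 2 h), 1617 and 1616 (7 shocks 2 h), 1744 and 1737 (1 shock 6 h), and 1737 and 1680.0 (7 shocks 6 h). For 7 shocks against 1 they were 1422 and 1798 at 2 h and 1785 and 1879 at 6 h, and for 6 h against 2 h 1581 and 1925 after 1 shock and 1633 and 1621 after 7. The time pair shared 282 higher, 390.0 lower and 619 opposite genes, the shock number pair 318, 393 and 609 with a correlation of 0.0238, and all 4 sham comparisons 271 and 242.

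With the top 25% by mean fewer genes were counted: 85 and 83, 99 and 107, 116 and 123, and 104 and 131 against sham in the same order, 104 and 124, and 136 and 162 for 7 shocks against 1, and 122 and 138, and 100.0 and 102 for time. The time pair shared 13 higher, 6 lower and 12 opposite, the shock number pair 10, 10 and 16, and all 4 sham comparisons 7 and 6. Immediate early medians became 1.65 and 1.29 (1 and 7 shocks, 2 h against sham) and -1.60 and -0.45 (6 h against 2 h), the effector median 0.98 (1 shock 2 h against sham), and VMH medians -0.040, 0.32 and 0.40 (1 and 7 shocks at 2 h, 7 shocks at 6 h). Oligodendrocyte (7 shocks against 1 at 6 h, -0.091), microglia (0.12) and circadian medians (-0.10, both 7 shocks 2 h against sham) reversed.

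With the pseudocount at the 25th percentile, 22 genes were higher in all 4 groups. With no pseudocount, Mob1a reversed for 7 shocks at 6 h against sham (0.90) and against 1 shock (0.17). Averaging probe sets gave the immediate early list 0.63 (1 shock 2 h against sham) and reversed Cntfr (7 shocks against 1 at 2 h, -0.24), Ganab (1 shock 6 h against sham, 0.042) and Gart (7 shocks against 1 at 6 h, -0.66). Leaving out cross-hybridising probe sets reversed Ganab against sham (-0.18, 1.76 and 0.82 for 7 shocks 2 h, 1 shock 6 h and 7 shocks 6 h) and over time (1.31 and 0.99 after 1 and 7 shocks), and Tgm2 (0.80 for 7 shocks 2 h against sham, 0.97 and 0.084 for 7 shocks against 1 at 2 h and 6 h). Leaving out 1 ECS array at a time gave 71 to 78 genes higher and 57 to 67 lower in all the rest, where fewer conditions must be met. For the other results that moved or reversed, the cause was not tested.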

Other observations

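None of the values here decides between explanations, and the marker lists of other brain regions were chosen after the arrays were examined. Some secreted signals of the hypothalamus, picked from the peptide list, read higher than the sham array on the other 4. The 4 differences share that 1 array, which was low for the list (-0.30 relative to the other arrays, percentile 0.36), so they do not count as independent. Scg2, the precursor of the granin peptide secretoneurin, was 0.78, 0.70, 0.90 and 0.95 above sham after 1 shock at 2 h, 7 shocks at 2 h, 1 shock at 6 h and 7 shocks at 6 h. The substance P gene Tac1 was 0.73, 0.61, 0.75 and 0.77 above it in the same order, and Penk 0.94, 1.14, 0.69 and 1.68. The granin Chga was highest after 1 shock at 6 h (0.90), and somatostatin, Sst, lay between -0.18 and 0.46. The metallothioneins Mt1 and Mt2, which bind zinc and copper, were 0.55 and 0.45 above sham after 1 shock at 2 h and 0.76 and 0.61 at 6 h, and Mt1 was -0.18 and -0.29 after 7 shocks.

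Among genes of the stress and growth lists, Ddit4, an inhibitor of mTOR signalling, was at -1.16 after 1 shock at 6 h and between -0.45 and 0.17 in the other groups. The glucocorticoid receptor gene Nr3c1 was at 0.83 after 1 shock at 6 h and between -0.59 and 0.31 by its probe sets after 7 shocks at 6 h. The ER chaperone Hspa5 lay between 0.06 and 0.59, and the chaperone regulator Creld2 was at 1.14 after 7 shocks at 2 h. Pdgfa was above sham by 1.34 after 1 shock at 2 h and by 1.02 after 7 shocks at 6 h.

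Markers of neighbouring regions were taken per array, relative to the other 4. On the single-shock 6 h array thalamus markers (5 genes) were at 0.43 (percentile 91.3) and mammillary markers (4 genes) at 0.30 (percentile 85.1), both within the central 95% of random lists. VMH markers on that array were at 0.50 (percentile 99.0). Of the region markers, the largest deviation was that of arcuate markers (4 genes) on the 7-shock 6 h array, at 1.08 (percentile 99.96), where cortex and amygdala markers were at 0.42 (percentile 99.7). A difference in what was dissected was not separated from an effect of the shocks for these.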
